A study of Drosophila melanogaster with 2 samples.

How the data were processed

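Whole wandering L3 larvae of a line with a C-terminal GFP fusion of CG9705 were assayed by ChIP-seq in 2 biological replicates, which per the labels are separate biosamples of 1 line with the sexes pooled. Chromatin was sheared by sonication to a size range of 200 to 800 bp, per the labels. The labels disagree on what the libraries are: the free-text description of both calls them an input control, while the antibody field names CG9705, the assay title is transcription factor ChIP-seq, a separate control experiment is listed, and per the deposited file notes each peak list was derived from the library's alignment together with 1 separate control file. The libraries are treated here as the ChIP samples. If the description were right, the lists would show sites enriched in sheared chromatin and not binding.

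Per the deposited file notes, the lists are in narrowPeak format on dm6: a relaxed list of peaks and background for each replicate and for the pool of both, and an optimal IDR-thresholded set derived from them. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The deposited score of a peak is the caller's signal value against the control; its scale is not stated. It was used to rank peaks within a list, to compare medians of promoter and distal peaks within a list, and to correlate shared peaks between the replicates; levels were not compared between lists. The deposited −log10 q value reaches the same highest value for 2929 pooled peaks, 3668 peaks of replicate 1 and 4301 of replicate 2, so it cannot rank the best 3533, and ranks come from the score. Each relaxed list holds 30000 peaks, and the optimal set equals the 3533 highest-scoring pooled peaks. Median widths were 380, 396 and 400 bp in replicate 1, replicate 2 and the pool. Peaks that share an interval but have different summits (52 in the pooled list) were kept apart. The files give no read counts and the signal tracks were not used here, so depth per sample is unknown and no interval based on it is given.

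Arm lengths and sequences of 2L, 2R, 3L, 3R, 4 and X came from RefSeq Release 6 of the genome, the assembly that dm6 carries; all peaks lay within these arms. Genes and transcript starts came from Ensembl release 115 (BDGP6.54), with transposable elements left out, which gave 23998 transcript starts and 13945 protein-coding genes. A summit took 1 class in the order promoter (within 500 bp of a start), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. A circular shift moved all peaks of an arm by 1 random distance, with 1000 shifts for main results and 20 to 200 for alternatives. Reciprocal overlap of at least 50% counted as shared. Log2 odds ratios have 0.5 added to each cell, and their p-values are from Fisher's exact test without it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

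The tests, 28 gene lists, 20 motif sequences and alternatives were fixed before the data were examined. Later, but before any peak was assigned to a gene, 19 older symbols were replaced by current ones, 2 genes that a name pattern had caught by mistake (Cp190 and Cp110) were taken off the chorion list, and transposable elements were left out of the transcript starts. Genes named in the text follow a rule fixed in advance: the 25 highest-scoring optimal peaks within 500 bp of a protein-coding start that overlap one of the 3533 best peaks in both replicates, named by the nearest start; the 5 strongest optimal peaks further than 500 bp from any start; up to 4 bound members of each list by score; and CG9705 and w. One of the list members so chosen is not reported here. Partner genes at head-to-head promoters were named after their values were seen. Two-sided tests were used except for replicate sharing. With 1 group of 2 samples, the error of each result is its value from the 3533 best peaks of each replicate alone, written as without the other replicate.

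The procedures were tested on simulated data. With 59.1% of 3533 peaks planted as shared, 59.6% were found shared. With bound shares of 60% in 5 planted lists of at least 30 genes and 20% elsewhere, 100% of planted lists were called over 50 draws of 13945 genes, 0.957% of the other lists were called, and with no list planted 0.143% were. Smaller lists and smaller differences were not planted, and genes were drawn independently of their neighbours. Most lists called as enriched in the data had bound shares below 60%, such as 34.6% for translation factors. The check therefore does not give the recovery of such lists. With 76.6% upstream among 1511 planted promoter peaks that lay nearest to their own gene, 74.1% were recovered upstream. Planted peaks nearer to another gene were left out of this check. A motif planted in 5.60% of 3533 windows was recovered in 5.60%, and 0 of 20 motifs were called with none planted. These windows and their flanks came from random positions. The simulation therefore does not cover calls that arise from the lower GC of real summits (34.2% against 44.5% in flanks). With 56.2% of summits in promoters the classes gave 56.2%, but both values use the same window around the same starts and had to be equal.

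Alternatives were other overlap rules and list sizes, the 1766 highest-scoring optimal peaks, each replicate left out, start windows of 250 and 1000 bp, other definitions of a peak's position, other backgrounds and other motif windows. A peak near several genes counts for each, and genes of a list that lie side by side are not independent, so p-values of gene lists are approximate.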

Results

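Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole wandering L3 larvae of Drosophila melanogaster, the last larval stage before pupation, with males and females pooled. The flies carried a transgene for CG9705 with green fluorescent protein (GFP) fused to its C terminus. CG9705 encodes a cold-shock domain protein, a family that binds single-stranded nucleic acids, and the question the experiment addresses is where in the larval genome the tagged protein is found. There were 2 biological replicates of 1 group, and no second group to compare them with. The deposited data were peak lists on the dm6 build: 30000 relaxed peaks for replicate 1, 30000 for replicate 2, 30000 for both replicates pooled, and an optimal set of 3533 peaks that passed the authors' filter for reproducibility between replicates (irreproducible discovery rate, IDR). The optimal set held the 3533 highest-scoring pooled peaks. The peak score is the authors' own and its scale is not stated, so its levels are not compared between lists. The lists give no read counts, so the depth of the libraries is unknown, and the binomial intervals below cover only the counting of peaks or genes.

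The strongest sites recurred in both replicates. The peak at the CG14100 promoter ranked first in the pooled list and in each replicate, and the peak at Ugalt, which encodes a UDP-galactose transporter, ranked second in all of them. Of the 100 best peaks of replicate 1, 83.0% lay at one of the 100 best of replicate 2, and of the 3533 best, 2435 (68.9%, 95% exact binomial interval 67.4 to 70.4%) did so with a reciprocal overlap of at least 50%. After circular shifts of replicate 2 along the chromosome arms the mean share was 0.716% and the highest of 1000 shifts was 1.25% (one-sided permutation p = 0.001, the smallest that the shifts can give). Across the 2435 shared peaks, which are not independent replicates, scores correlated with Spearman's rho of 0.830 and with Pearson's r of 0.909 on log2 scores. Across all 14065 peaks shared by the relaxed lists the coefficients were lower, at 0.686 and 0.815. How many optimal peaks found a match depended on peak width: 569 optimal peaks were narrower than 200 bp, and only 27.1% of these overlapped a replicate 1 peak reciprocally by 50%, while 97.9% had a replicate 1 summit within 100 bp. The optimal set was itself drawn from these replicates, so these shares describe the matching rule and not recurrence.

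Promoters were the main location of the peaks, and coding sequence was nearly empty of them. In the optimal set 2053 summits (58.1%, 95% exact interval 56.5 to 59.7%) lay within 500 bp of an annotated transcript start, against a mean of 13.6% after circular shifts, a ratio of 4.28 (two-sided permutation p = 0.002, the smallest that the shifts can give). The share was 56.0% among the 3533 best peaks of replicate 1 and 59.98% among those of replicate 2. Introns held 1009 summits (28.6% against 39.4% after shifts) and intergenic sequence 405 (11.5% against 27.4%). Coding exons further than 500 bp from any transcript start held 7 summits, or 0.198% against 13.1%, and 3' UTRs held 24, or 0.679% against 5.04%. For each of these 5 classes the two-sided permutation p was 0.002, the smallest that 1000 shifts can give, and the Benjamini-Hochberg adjusted p over 7 classes was 0.0028. The 5' UTR held 14 summits (0.396% against 0.779%, permutation by shifts, adjusted p = 0.014) and other exons 21 (0.594% against 0.808%, adjusted p = 0.20). The 5' UTR difference did not pass the threshold in the 1766 highest-scoring optimal peaks or in replicate 2 alone. Its ratio to the shifts was 0.508 in the main setting, 0.438 in the 1766 peaks and 0.771 in replicate 2 alone.

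**Figure D1:**
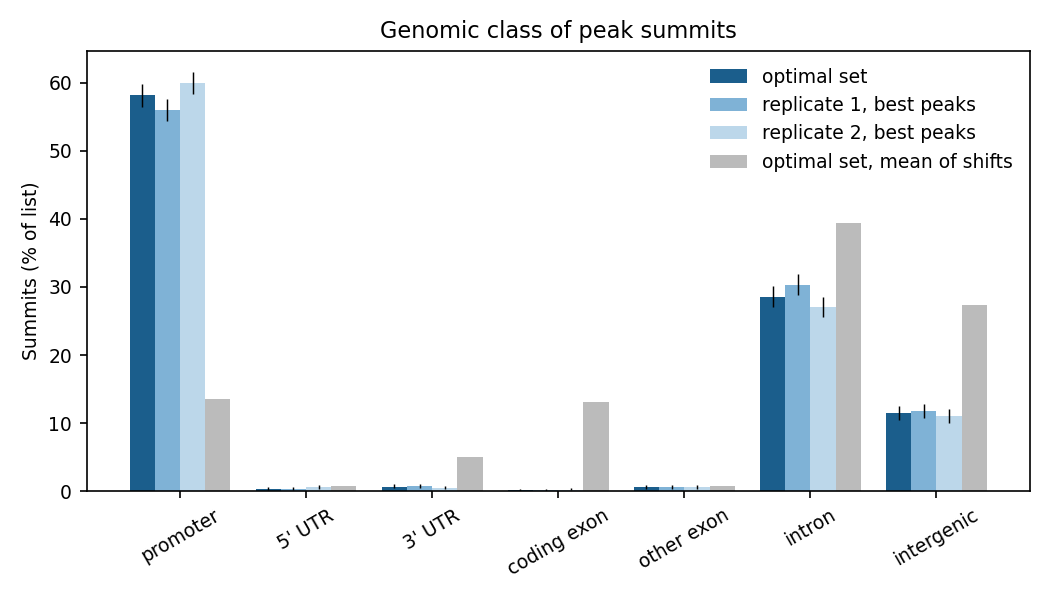
Share of peak summits in each genomic class (y axis, % of the list) for the optimal set, the 3533 best peaks of each replicate and the mean of the circular shifts of the optimal set (grey). Error bars are 95% exact binomial intervals; promoters hold 58.1% of optimal summits against 13.6% after shifts, and coding exons 0.198% against 13.1%.

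The promoter share fell with rank in the pooled list. It was 50.5% for ranks 3534 to 7500, 34.4% for ranks 7501 to 15000 and 22.0% for ranks 15001 to 30000. Over the same steps coding exons went from 0.302% to 2.92% and 6.76% of summits. All 26467 relaxed peaks outside the optimal set had 29.8% of their summits at a transcript start, and the log2 odds ratio of the optimal set over them was 1.71 ± 0.05 (SE; Fisher's exact test, two-sided, p = 1.97e-232).

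The 25 strongest promoter peaks shared by both replicates named 24 genes of mixed function. The peak at CG14100 (chromosome 3L, 19590382 to 19590838) had its summit at -85 bp from the transcript start (negative is upstream) and a score of 4711, and the peak at Ugalt (X, 2703676 to 2704114) had its summit at -37 bp and a score of 3377. They were followed by mRpL41, a mitochondrial ribosomal protein (score 2398), CG1888 (2226) and Art3, an arginine methyltransferase (2182). Metabolic genes among the 25 were Gapdh2, a glycolytic dehydrogenase (score 1953, summit at -166 bp), Lpin, the phosphatidate phosphatase Lipin (1053, at -252 bp), and CIA30, a complex I assembly factor (1412, at -103 bp). Regulators of transcription were ph-p, a subunit of Polycomb repressive complex 1 (scores 2039 at -464 bp and 1072 at 425 bp, each from the start nearest to it), Sox14, an ecdysone-induced HMG-box factor (1603, at -245 bp) and bbx, another HMG-box gene (1082, at -198 bp). Genes of translation, trafficking and the cytoskeleton were eIF6, which acts in assembly of the large ribosomal subunit (1510), Arl1, a Golgi GTPase (1217), and Atat, a tubulin acetyltransferase (1162). The others were CG11309, Pal1, CG18549, Tcs5, CG18428, CG13921, CG13390, CG3552, CG5611 and CenG1A, with scores from 1917 to 1293. None of the 25 ranked below 50 in replicate 1 or below 47 in replicate 2. Of these peaks 12 lay within 500 bp of transcript starts of more than 1 protein-coding gene, so that the peak named for Art3 was also that of mRpS10 (at -132 bp) and the peak named for Arl1 was that of brm (at -139 bp), which encodes the ATPase of the fly SWI/SNF complexes.

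The 5 strongest peaks further than 500 bp from any transcript start ranked between 3 and 11 in the pooled list. The highest was in an intron of CG11050 (2L, 6612471 to 6612923, score 2811), 1029 bp downstream of a start. The others lay in introns of CG9663 (2L, 3301939 to 3302615, score 2077), Tlk, a chromatin-associated kinase (X, 3742004 to 3742415, score 2055), and Lk6, a kinase of the translation factor eIF4E (3R, 11760839 to 11761250, score 2010), and in intergenic sequence at -1294 bp from DNAlig3, a DNA ligase (3R, 12402932 to 12403334, score 2435). All of them ranked among the 15 best peaks of each replicate.

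Genes for cytoplasmic ribosomal proteins stood apart from other genes. A gene was counted as bound if an optimal summit lay within 500 bp of one of its transcript starts, as held for 2661 of 13945 protein-coding genes (19.1%). Of 86 cytoplasmic ribosomal protein genes, 72 were bound (83.7%, 95% exact interval 74.2 to 90.8%), among them RpS27 (score 1036), RpL34b (767), RpL7 (767) and RpL13A (644). The log2 odds ratio against other genes was 4.44 ± 0.42 (SE; Fisher's exact test, two-sided, Benjamini-Hochberg over 28 lists, adjusted p = 5.38e-37), with 69 bound from replicate 1 alone and 73 from replicate 2 alone. Polycomb and trithorax group genes, which maintain repressed and active chromatin states, were bound in 17 of 30 cases (56.7%, log2 odds ratio 2.47 ± 0.52, Fisher's exact test, adjusted p = 3.68e-05), led by ph-p, brm, E(z) (531) and lola (510). Both lists passed the threshold in each of the 9 alternative settings, including a background of only those genes with a relaxed or optimal peak at a start, where their log2 odds ratios were 3.69 and 1.92.

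Another 7 lists had a higher bound share than other genes in the main setting. Mitochondrial ribosomal protein genes were bound in 29 of 73 cases (Fisher's exact test, adjusted p = 0.000208; mRpL41, mRpS10, mRpS23 and mRpL23), growth signalling genes of the Hippo and insulin pathways in 11 of 25 (0.0137; hpo, Mer, kibra and Rheb) and splicing genes in 14 of 36 (0.0155; U2af50, BCAS2 and SF2). Genes of mRNA decay and mRNP regulation were bound in 15 of 40 cases (0.0187), with the highest score at yps (628), which encodes the Y-box cold-shock protein Ypsilon schachtel, followed by gw, Unr, another cold-shock domain protein, and AGO1. Translation factor genes were bound in 18 of 52 cases (0.0187; eIF4EHP, eIF6, eEF1gamma and eIF1), proteasome genes in 12 of 32 (0.0281; Rpn5, Rpt5, Rpn3 and Prosbeta2) and ecdysone response genes in 11 of 28 (0.0281; Eip75B, hid, E23 and Eip63F-1). With only genes that had a relaxed or optimal peak as background, none of these 7 passed the threshold (adjusted p from 0.344 to 0.752). In the 1766 highest-scoring peaks only splicing kept its call (0.00492), while the log2 odds ratio was 0.79 for mitochondrial ribosomal proteins, 0.67 for mRNA decay, 0.40 for growth signalling and 0.0035 for the proteasome, and stayed near the main value for ecdysone response (1.56) and translation factors (1.07). With each peak given to its nearest start only, the call was lost for mitochondrial ribosomal proteins (log2 odds ratio 0.31, adjusted 0.63), the proteasome (0.98, 0.314) and splicing (1.22, 0.121). It was lost for growth signalling (0.338) and ecdysone response (0.793) with a 250 bp window, and, with log2 odds ratios of 1.23, 1.26 and 1.1504, for splicing (0.0536), ecdysone response (0.0702) and the proteasome (0.0808) with a 1000 bp window. From 1 replicate alone it was lost for translation factors in replicate 1 (log2 odds ratio 1.03, adjusted 0.0613) and for the proteasome (1.13, 0.0891) and ecdysone response (1.22, 0.0952) in replicate 2.

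Genes for cuticle, eggshell, chemoreception, digestion and imaginal disc patterning were rarely bound. None of 113 cuticle protein genes was (0%, upper 95% exact bound 3.21%, adjusted p = 4.83e-10), nor any of 21 chorion, vitelline membrane and yolk genes (upper bound 16.1%, adjusted p = 0.0445). Chemosensory receptors were bound in 1 of 179 cases (Ir60e, Fisher's exact test, adjusted p = 2.87e-14), midgut digestive enzymes in 1 of 40 (Mal-A5, 0.0137) and imaginal disc patterning genes in 3 of 61 (bowl, aos and so, 0.013). Against genes with a relaxed or optimal peak as background only the imaginal disc list passed the threshold (3 of 44 genes, Fisher's exact test, adjusted p = 0.000279). The log2 odds ratios stayed below 0 for the 12 cuticle genes (-3.78, adjusted 0.0733) and 16 chemosensory receptor genes (-2.51, adjusted 0.0733) left to test. In all other alternatives the cuticle and chemosensory lists kept their calls. The chorion, midgut and imaginal disc lists lost theirs in the 1766 highest-scoring peaks (adjusted 0.346, 0.312 and 0.227) and with the nearest start only (0.215, 0.14 and 0.191). The chorion list also lost it with a 250 bp window (0.126) and in replicate 1 alone (0.0522), as did the imaginal disc list in replicate 1 alone (0.0835). In replicate 1 alone the bound genes were still 0 of 21 for the chorion list and were 5 of 61 for the imaginal disc list.

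The other 14 lists did not pass the threshold in the main setting. Glue and late puff genes of the salivary gland had 1 of 22 genes bound (Sgs5), muscle structure 1 of 25 (Msp300), hemocytes 1 of 16 (PPO3), calcium signalling 1 of 20 (Plc21C), germline and testis 2 of 31 (bgcn and nanos), neuronal function 2 of 25 (Syx1A and elav, the pan-neuronal RNA-binding protein, with a score of 1031) and the Hox genes 0 of 8. The bound members were 5 of 22 for the fat body (Glyp, bmm, FASN1 and mdy with the highest scores), 3 of 12 for glia (moody, Gli and loco), 3 of 11 in the Enhancer of split complex, 4 of 10 circadian clock genes (sgg, cry, dco and vri), 6 of 28 heat shock and chaperone genes (Hsp27, Hsp83, Hsc70-5 and Droj2 highest), 13 of 41 for DNA replication and cell cycle (RnrS, CycE, PCNA2 and dup highest) and 19 of 78 for oxidative phosphorylation (ND-ASHI, ND-MWFE, ND-42 and ND-SGDH highest). Their adjusted p ranged from 0.0869 for DNA replication to 0.809 for heat shock genes. From replicate 2 alone no glue or late puff gene was bound, and this list passed the threshold as depleted (log2 odds ratio -3.46, Fisher's exact test, adjusted p = 0.0314).

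**Figure D2:**
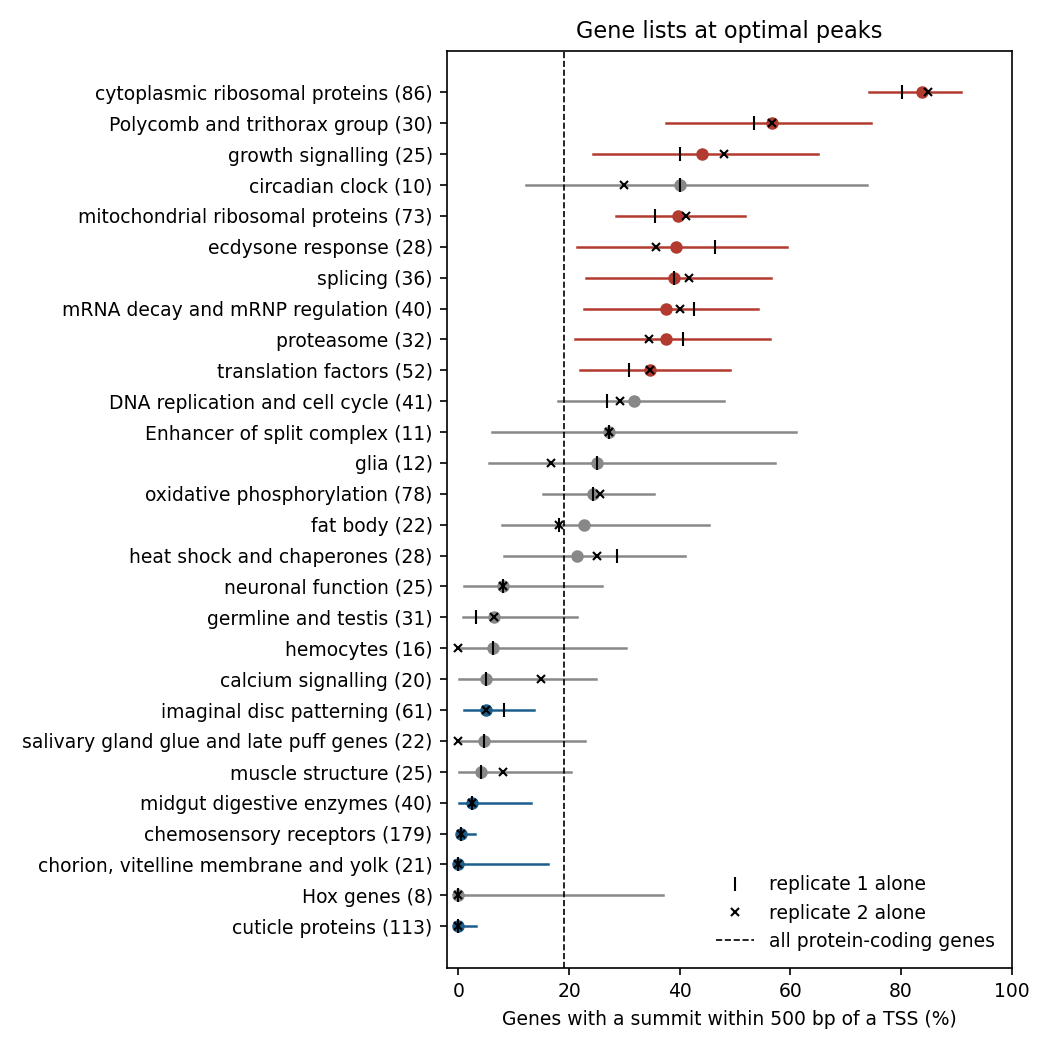
Share of genes with an optimal summit within 500 bp of a transcript start (x axis, %) for each of the 28 gene lists, with the number of genes in parentheses; bars are 95% exact binomial intervals. Red lists were above and blue lists below other genes at an adjusted p under 0.05, ticks and crosses give each replicate alone, and the dashed line marks 19.1% of all protein-coding genes.

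At promoters the summits lay upstream of the transcript start. Of 2053 promoter summits, 1698 were upstream of the nearest start, 353 downstream and 2 at the start itself, so that 82.8% of those off the start were upstream (95% exact interval 81.1 to 84.4%; exact binomial test, two-sided, p = 2.51e-210). The share was 82.5% in replicate 1 and 82.6% in replicate 2. A summit between 2 head-to-head starts is upstream of both, and 857 optimal peaks had at least 2 protein-coding genes within 500 bp. Part of the upstream share can therefore follow from gene arrangement, which the binomial test does not take into account. Promoters without a head-to-head partner were not tested apart. The median position was -98 bp (interquartile range -172 to -30 bp), and the fullest 20 bp bin ran from -120 to -100 bp with 211 summits. Of the 25 named promoter peaks, 23 lay upstream.

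**Figure D3:**
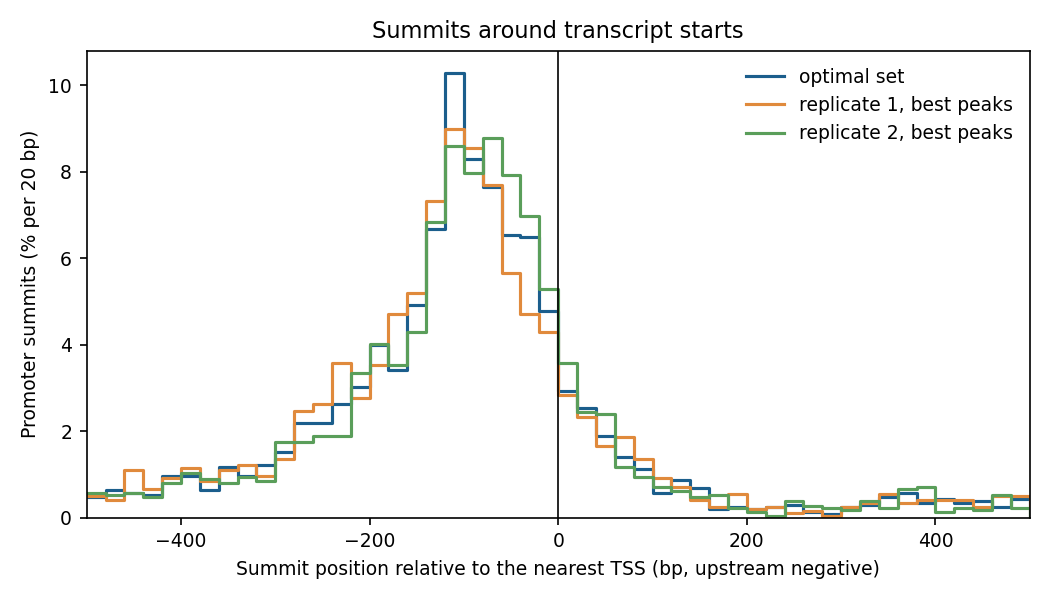
Position of promoter summits relative to the nearest transcript start (x axis, bp, upstream negative) as the share of promoter summits per 20 bp (y axis, %), for the optimal set and the 3533 best peaks of each replicate. All of the curves peak upstream of the start, and the optimal set has its median at -98 bp.

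Head-to-head gene pairs, in which transcription runs outward from a shared promoter region, were bound more often than other genes. Among 3815 protein-coding genes with an opposite-strand start within 500 bp upstream, 1569 were bound (41.1%), against 1092 of 10130 others (10.8%), a log2 odds ratio of 2.53 ± 0.07 (SE; Fisher's exact test). The p-value lies below what double precision can hold, and its −log10 by the upper tail of the hypergeometric distribution was 327. Examples from the named peaks are Art3 with mRpS10, Arl1 with brm, Tcs5 with CHMP2B, and CIA30 with CG7601. A peak between 2 such starts counts for both genes, and 857 optimal peaks had at least 2 protein-coding genes within 500 bp against 1105 with 1. The genes of a pair are therefore not independent, and the p-value overstates the evidence. Part of the higher share can follow from this counting, and no setting that counts each peak for only 1 gene was run for this comparison.

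Chromosome 4, which is small and largely heterochromatic, held 11 optimal peaks, 0.422 times the number its protein-coding transcript starts would give (exact binomial test, two-sided, Benjamini-Hochberg over 6 arms, adjusted p = 0.00916); gw was among the genes bound there. The X held 638 peaks, or 27.1 per Mb, a ratio of 1.06 to its share of transcript starts that did not pass the threshold (exact binomial p = 0.0976, adjusted p = 0.146). The ratio was 0.903 on 2R (exact binomial, adjusted p = 0.00983) and 1.09 on 3L (adjusted p = 0.0187), and 2L and 3R had ratios of 0.982 and 0.999. The chromosome 4 call was lost in replicate 2 alone (15 peaks, exact binomial, adjusted p = 0.089) and in the 1766 highest-scoring peaks (adjusted p = 0.15). The 2R and 3L calls were lost in the 1766 highest-scoring peaks, with expected shares from chromosome length and with those from relaxed peaks, and the 2R call also in replicate 2 alone. With relaxed peaks as the expectation the ratios turned, to 1.07 on 2R (exact binomial, adjusted p = 0.0946) and 0.959 on 3L (0.201), and 3R passed the threshold with 1.09 (0.0164).

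Promoter peaks scored slightly higher than distal ones. The median score was 173 at 2053 promoter peaks and 160 at 1480 distal peaks, a ratio of 1.08 (permutation test of the difference in medians, two-sided, 100000 resamples, p = 0.00209; peaks are not independent replicates). The ratio was 1.06 in replicate 1 and 1.07 in replicate 2. In the 1766 highest-scoring optimal peaks it was 1.02 (permutation p = 0.484).

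Sites for DREF, CTCF and Su(Hw), factors of housekeeping promoters and of insulators, were more frequent at summits than beside them. The DREF site (DRE, TATCGATA) was found within 50 bp of 87 summits (2.46%, 95% exact interval 1.98 to 3.03%) against 0.623% of flanks centred 300 bp away (exact McNemar test, Benjamini-Hochberg over 20 motifs, adjusted p = 1.6e-09). Its excess lay at promoter peaks (4.14% of summits against 0.974% of flanks), while at distal peaks summits and flanks both had 0.135%. The excess may therefore reflect the position of these peaks at promoters. The CTCF core was found at 50 summits (1.42% against 0.226%, exact McNemar test, adjusted p = 7.85e-08) and the Su(Hw) core at 38 (1.08% against 0.396%, adjusted p = 0.00208). The core promoter element Motif 7 was at 3.26% against 1.53% (exact McNemar test, adjusted p = 7.69e-06), Motif 6 at 0.425% against 0.113% (0.032) and the BEAF dual site at 9 summits against 0.0283% of flanks (0.0331). GATA sites were at 21.8% of summits against 14.01% of flanks (3.05e-16) and the TATA box at 2.35% against 1.16% (0.00045). Summit windows were AT-rich, with 34.2% GC against 44.5% in flanks, and after shuffles that kept dinucleotide counts 25.02% of summit windows had a GATA site and 2.59% a TATA box. The Su(Hw) core, Motif 6 and the BEAF site were not compared with shuffled windows, so base composition may account for their excess. In the 1766 highest-scoring peaks the call was lost for Motif 7, Motif 6 and the BEAF site. From replicate 2 alone it was lost for Motif 6 and the BEAF site, and from replicate 1 alone for the BEAF site.

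Repeats and GAGA sites were less frequent at summits than in flanks. GAGAGAG was at 1.10% of summits against 2.86% (exact McNemar test, adjusted p = 4.29e-07), the CA repeat at 0.453% against 2.01% (1.3e-08) and the CTG repeat at 3 summits against 0.962% (4.29e-07). The E-boxes CAGCTG (3.57% against 4.87%, 0.0154) and CACGTG (0.679% against 1.27%, 0.0281) and the initiator (7.93% against 9.43%, 0.0405) were also lower, each with a loss of the call in at least 2 of 5 alternatives. Summit windows had less GC than flanks (34.2% against 44.5%), and none of these less frequent motifs was compared with shuffled windows. Base composition may therefore account for these differences. The inverted CCAAT sequence ATTGG, a motif linked with Y-box cold-shock proteins, was at 17.2% of summits and 17.7% of flanks (exact McNemar test, adjusted p = 0.648). The Zelda site, the ecdysone receptor palindrome, the nuclear receptor site AAGGTCA, AP-1 and Motif 1 did not pass the threshold either, with adjusted p from 0.0581 for Motif 1, which passed it in 4 of 5 alternatives, to 1 for the palindrome; the Zelda site passed in 2 alternatives and AAGGTCA in 1.

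Bound promoters differed in core elements from promoters with only a weaker peak. From 100 bp upstream to 50 bp downstream of the start, Motif 7 was present in 16.2% of 2661 bound genes against 8.20% of 4854 genes with a relaxed peak only, a log2 odds ratio of 1.11 ± 0.11 (SE; Fisher's exact test, Benjamini-Hochberg over 20 motifs, adjusted p = 9.39e-24). The E-box CAGCTG was at 17.7% against 14.3% (0.37 ± 0.09, Fisher's exact test, adjusted p = 0.000551). The initiator was less frequent, at 16.6% against 24.7% (-0.71 ± 0.09, Fisher's exact test, adjusted p = 3.23e-15), as was the TATA box at 2.41% against 4.88% (-1.05 ± 0.21, adjusted p = 4.66e-07). The DRE did not differ past the threshold (11.6% against 10.7%, Fisher's exact test, adjusted p = 0.359), but against all unbound protein-coding genes (6.35%) it did, with a log2 odds ratio of 0.95 (adjusted p = 6.05e-18). Of the 2661 bound genes, 1569 had a head-to-head partner. Close pairs can share promoter sequence, so the genes are not independent and these p-values are approximate. Gene arrangement was not taken into account in this comparison.

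At the tagged gene itself there were 2 optimal peaks within 5 kb. CG9705 lies at 16780100 to 16782419 on the plus strand of chromosome 3L. The stronger peak (16779725 to 16779891, score 268, rank 883) had its summit at -285 bp from the CG9705 start, and nearer, at -79 bp, to the start of mus302, a DNA repair gene on the other strand. The other peak (16782332 to 16782731, score 223, rank 1167) lay at the 3' end of CG9705, at -478 bp from CG9706. The upstream site ranked 1190 in replicate 1 and 757 in replicate 2. Near w, a gene often carried by transgenes as a marker, the closest optimal peaks (X, 2787251 to 2787580, rank 613, and 2786674 to 2786883, rank 971) lay beyond the 3' end of w in intron sequence. Their nearest start was that of CG32795, and both peaks and w lie within the span of kirre. Scores at these loci were not tested.

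**Figure D4:**
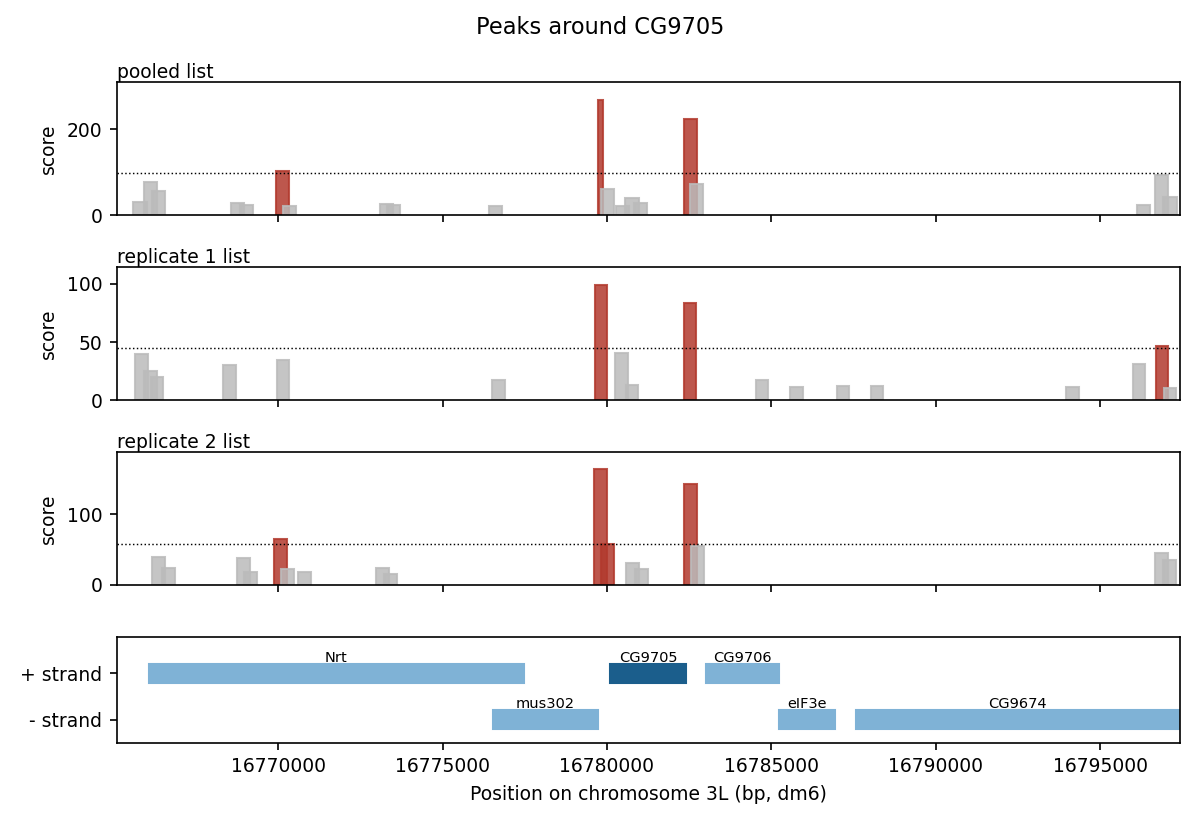
Peaks around CG9705 on chromosome 3L (x axis, bp, dm6) in the pooled list and each replicate; the height of a bar is the authors' score (y axis, separate for each list), its width the peak, red bars are among the 3533 best of their list and the dotted line is the score at that rank. Genes are drawn below by strand, and the peaks on either side of CG9705 are red in all of the lists.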

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

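All alternatives reported here were chosen before the data were examined. Of 64 alternative values of the main results, 54 kept their direction and side of the threshold, or stayed within 1.5 times the main count. They include each alternative for the share of replicate peaks (46.9 to 79.5%), the promoter share (48.1 to 67.4%), the upstream share (82.5 to 84.8%) and head-to-head promoters (log2 odds ratio 1.89 to 2.52). In the 1766 highest-scoring peaks, 3 lists were enriched and 2 depleted, 5 motifs were more frequent at summits and the promoter to distal ratio was 1.02 (permutation p = 0.484). This set has fewer peaks, and some log2 odds ratios were also lower, such as 0.0035 for the proteasome; the cause was not tested. With genes that had a relaxed or optimal peak as background, 2 lists were enriched and 1 depleted, with fewer genes tested and log2 odds ratios of 0.33 to 1.146 in the 7 lists that lost the call. With the nearest start only, 2 lists were depleted, and from single replicates 3 to 6 were. Against all unbound genes, 8 motifs were more frequent at bound promoters than the 2 of the main setting. The X ratio turned to 0.939 with relaxed peaks as the expectation (exact binomial p = 0.0765), without passing the threshold in either; the cause was not tested.

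Of 503 values for single lists, motifs, classes and peaks, 26 changed sign; none of these had passed the threshold in the main setting, and the cause was not tested. Log2 odds ratios turned for oxidative phosphorylation (-0.26), heat shock (-0.0766) and fat body (-0.20) with the background of genes with peaks, from single replicates for fat body (-0.00936 to 0.131) and glia (-0.0402 to 0.731), for glia (-0.51) and the Enhancer of split complex (-2.09) with the 250 bp window, and for that complex (-0.0611) with the nearest start. At bound promoters they turned in the 1766 highest-scoring peaks for the DRE (-0.0746), GAGA (0.0558), CTCF (0.34), Su(Hw) (0.50), BEAF (-1.17) and AP-1 (0.34), and from single replicates for the DRE (-0.00374 to 0.199), GAGA (-0.308 to 0.16) and CTCF (-0.0169 to 0.00303). Against all unbound genes they turned for Motif 1 (0.61, Fisher's exact test, adjusted p = 3.5e-05, although it was -0.63 in the 1766 highest-scoring peaks, adjusted 0.00376, and -0.39 without replicate 2, adjusted 0.0252), Motif 6 (0.52, adjusted p = 0.0484), GAGA (0.20), CTCF (0.39), Su(Hw) (0.0445) and the ecdysone receptor palindrome (-0.24). At summits the palindrome (0 to 0.0566% from single replicates and 0.0283% with flanks 500 bp away) and AP-1 (1.02% in the 1766 highest-scoring peaks) turned. A ranking by the q value was planned and could not be run, because its ties exceed the number of peaks compared. No paired analysis was possible because there is 1 group. The unknown depth limits all of these results: a relaxed list of fixed length fills with background at any depth.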

Other observations

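The tests on tissue-restricted genes, oxidative phosphorylation genes and peak density at the tagged locus were chosen only after related values had been seen, and the comparisons of replicate ranks, of noncoding genes other than those for transfer RNA, of motifs between promoter and distal peaks, of genes with many peaks and of narrow peaks were likewise added after seeing the data. The comparison of AAATAT with shuffled sequence was set up after its share over flanks was known.

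The protein-coding genes with the most optimal summits were of very different length, and no test of clustering was made. The most summits within 1 protein-coding gene were 13 each in kirre, a cell adhesion gene of 394 kb, and CG1677 (125 kb), followed by 11 in sbb (79.1 kb), or 0.33, 1.04 and 1.39 per 10 kb. Summits were counted over the whole span of a gene, including other genes within it, so the count for kirre includes the optimal peaks near w. CHES-1-like, a forkhead gene, held 9 in 27.0 kb (3.33 per 10 kb) and tara held 9 in 34.7 kb (2.60 per 10 kb). The ecdysone-induced receptor gene Eip75B held 8 in 114 kb, and Eip74EF and Hr4, which are also ecdysone-regulated, held 7 each. Other genes had equal counts: shn and Tlk held 9 each, Svil, Tet and Raf 8 each, and Mnt 7. Whether ecdysone-regulated genes hold more summits than others was not tested. Of 3261 genes annotated as ncRNA, 169 (5.18%) had an optimal summit within 500 bp of a start, against a mean of 2.67% after 200 shifts (permutation p = 0.00995, the smallest these shifts can give). For protein-coding genes the shares were 19.1% and 3.12%. Of the 2053 summits at any start, 1962 were at a protein-coding one. A summit at a protein-coding promoter also counts for an ncRNA gene beside it, and such ncRNA genes were not set apart. The other noncoding classes did not pass the threshold: 13 of 269 snoRNA genes (permutation p = 0.209), 2 of 32 snRNA genes (0.438) and 0 of 99 rRNA genes (1).

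The DRE and Motif 7 were more frequent at promoter than at distal summits. The DRE was at 85 of 2053 promoter summits and 2 of 1480 distal ones (Fisher's exact test, Benjamini-Hochberg over 20 motifs, adjusted p = 7.37e-17), and Motif 7 at 101 and 14 (adjusted p = 3.21e-11). Motif 1, Motif 6 and both E-boxes also passed the threshold in this direction. The initiator went the other way, at 6.97% and 9.26% (Fisher's exact test, adjusted p = 0.0345), and the TATA box did not pass (adjusted 0.287). The CTCF core was at 28 promoter and 22 distal summits (Fisher's exact test, adjusted p = 0.815) and the Su(Hw) core at 20 and 18 (adjusted p = 0.682). GATA sites were at 20.1% of promoter and 24.1% of distal summits (Fisher's exact test, adjusted p = 0.0165). At distal peaks neither the DRE (0.135% of summits and of flanks) nor Motif 7 (0.946% against 1.08%) was above its flanks.

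Peaks at cytoplasmic ribosomal protein genes ranked higher in replicate 2 than in replicate 1. This held for 67 of 74 such peaks with a summit in both replicates, with a median log2 ratio of rank 1 to rank 2 of 0.84, against 0.05 (95% range -0.12 to 0.24) in 10000 draws of promoter peaks of like pooled rank (two-sided permutation p = 2e-04, the smallest these draws can give, adjusted over 9 lists 0.0018). The median was 0.26 for mitochondrial ribosomal proteins (permutation, adjusted p = 0.481) and 0.41 for translation factors (adjusted p = 0.35). None of the other 6 lists compared passed the threshold. The draws are over peaks, so the p covers only these 2 libraries and says nothing of others.

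The bound state of ribosomal protein genes was set against other features of their promoters. Head-to-head arrangement does not account for it: among genes without such a partner 41 of 52 ribosomal protein genes were bound against 10.4% of other genes, a log2 odds ratio of 4.95 ± 0.48 (SE). Signal at any strongly transcribed gene stays open: glue, fat body, muscle, cuticle and midgut genes together were bound in 8 of 222 cases (3.60%, upper 95% exact bound 6.98%), below the 19.3% of other genes. But 113 of them are cuticle genes with none bound, 5 of the 22 fat body genes were bound (22.7%), and how strongly any of these genes is transcribed in the larvae was not measured here. Strong transcription in all tissues stays open as well, because oxidative phosphorylation genes, at 24.4% bound (95% exact interval 15.3 to 35.4%), lay neither clearly above nor below other genes, and no expression values, mock ChIP or other factor were used here. This list also holds paralogs whose names end in an added L, such as COX4L, ND-24L and UQCR-14L, and none of these was bound. Whether they are transcribed in all tissues was not measured, so the share of the whole list cannot decide the question.

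Summits were rich in A and T, and this may account for part of the sequence content. GATA sites, at 21.8% of summits, were at 25.02% of summit windows shuffled with their dinucleotide counts kept, so base composition suffices for their excess over flanks. The TATA box was likewise at 2.35% of summits and 2.59% of shuffled windows. The DRE was at 2.46% of summits against 0.195% of shuffled windows (at most 0.396% in 20 shuffles). The CTCF core was at 1.42% against 0.102%, and Motif 7 at 3.26% against 0.579%. Su(Hw) and the remaining motifs were not shuffled. The 6-base sequence most in excess over flanks in 883 of the 1766 highest-scoring peaks, AAATAT, was at 35.6% of summits and 14.8% of flanks in the other 883 peaks (exact McNemar p = 3.54e-22), but at 26.3% of shuffled windows against 36.0% of all 1766 real ones, so composition gives much but not all of it. In the 883 peaks used for the search, the sequence with the lowest exact McNemar p over shuffled windows was TATCGA, the core of the DRE. In the 883 peaks not used to find it, TATCGA was at 7.93% of summits and 4.08% of shuffled windows (exact McNemar p = 0.000588, adjusted over 10 sequences 0.00147). Other sequences of the 10 had lower p there, such as AAATAT at 35.6% against 26.3% (exact McNemar p = 3.21e-06). CCGGAA was at 3.62% against 0.680% (exact McNemar p = 1.29e-05), though its flank share was 2.94%.

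The number of relaxed peaks around CG9705 was above the median but did not reach the limit set for it. A window of 12320 bp around the gene held 8 pooled relaxed peaks, against a median of 3 around protein-coding genes, and 86.6% of genes had fewer. This is under the limit of 95% chosen, after related values had been seen, for calling no effect of extra transgene copies on peak number. It does not exclude an effect of such copies, because the count takes no account of peak scores. Whether such copies raised the scores there was not tested.

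The idea that optimal summits also lie at genes transcribed by RNA polymerase III was tested on transfer RNA genes. Of 290, 10 had an optimal summit within 500 bp (3.45%), below the upper 2.5% of the shifts (4.84%), with a mean of 2.48% after shifts, so an excess was not detected.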
